A study of Mus musculus with 5 samples.

How the data were processed

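Single-cell RNA sequencing was done on tumours grown from SSM2 cells, a mouse mammary tumour cell line, in the fourth mammary gland of mice that carried a pellet releasing progesterone or a placebo pellet. Per the labels' protocols, tumours were dissociated with enzymes, red cells were lysed, and libraries were made with a droplet kit that reads the 3' end of transcripts and tags each molecule with a unique molecular identifier (UMI). The 5 libraries were 2 placebo and 3 progesterone libraries in 2 batches that the sample titles name. Batch 1 held Placebo 1 and Progesterone 1, and batch 2 held Placebo 2, Progesterone 2 and Progesterone 3. The labels do not say that the 5 libraries came from separate animals. The deposited names of Progesterone 2 and Progesterone 3 share an identifier and differ by the letters L and R, so p-values measure only the spread between these libraries, which may be technical or lie within 1 animal.

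The deposited matrices held counts, whole numbers of UMIs per gene and barcode, which were used as deposited with no normalisation by the authors. Cell Ranger 8.0.1 was the counting software per the file headers, while the submitters' processing notes name Cell Ranger 7.0.0 and the mm10 build. Every deposited barcode had at least 500 UMIs. The matrices had 24860 gene symbols with no mitochondrial genes among them, so the planned limits of 20% and 10% mitochondrial UMIs could not be applied. Markers absent from this set of symbols, such as the constant segments of the T cell receptor chains, were not used here. No column without a sample was used. Coordinates are those of the GENCODE M21 annotation on the GRCm38 build, which is the same assembly as mm10, and start from 1.

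Cells with at least 250 genes were kept. Doublets were scored against simulated doublets in each library and removed at a rate proportional to the barcodes in the library, which took out 1.79% to 4.68% of barcodes per library (40 to 274 barcodes). Counts were scaled to a common total and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components and 20 neighbours were passed to Leiden clustering at resolution 1. No batch integration was applied. Clusters were named from marker genes fixed before the data were examined, and a name with the ending "like" states marker expression, not lineage. T and NK cells were clustered again to split them into sub-classes. A cluster stayed unnamed where its marker score was low, where it had fewer than 3 detected markers, or where another class scored too close to the best. Macrophage and monocyte scores were not set against each other in this last rule, so the macrophage class may hold monocyte-like cells. A cluster also stayed unnamed where its median UMI count was under 1/3 of its library's and none of the name's markers led it. A T or NK sub-cluster stayed unnamed where its leading genes held more markers of another class than of its own. One sub-cluster of T cells was led by keratin genes and was taken out of the T cells after the data were examined, under a limit of 3 markers of another class among its 10 leading genes. Unnamed cells numbered 408 in Placebo 1, 660 in Progesterone 1, 1412 in Placebo 2, 1069 in Progesterone 2 and 1095 in Progesterone 3 in the clustering of all cells. Of these, 172, 271, 1204, 771 and 744 scored highest for epithelial markers, in the same order of libraries.

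Raw counts were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersions, TMM scaling, filterByExpr, prior count 2, batch as a covariate), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. The rule fixed before the data were examined asked for 20 cells of a class in every library, and the T cells alone met it. The other classes were tested under a rule added afterwards, over the libraries with at least 10 cells of the class. Epithelial cells, fibroblasts and both kinds of dendritic cell then lacked Placebo 1. With the batch term, those fits compared 1 placebo library with 2 progesterone libraries of batch 2 and had 1 residual degree of freedom, and the lone placebo library was assumed to vary like the others. B cells lacked Progesterone 3 and also had 1 residual degree of freedom. Macrophage and T cell fits had 2. Cell shares were tested with edgeR on cells per class, with exact Clopper-Pearson intervals at 95% for single libraries. Intervals and limits for a count of 0, set at 3 counts, cover counting error only. An exact permutation within batches has 6 arrangements and cannot go below p = 0.167, and without batches 10 arrangements reach 0.1.

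Gene lists, 27 in all, were fixed before the data were examined. A list with at least 4 tested genes was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists of a class. With an estimated correlation the camera test has no more degrees of freedom than the fit, here 1 or 2. A list could hardly pass it, so the loss of a call there decides little. The difference of the progesterone effect between epithelial cells and macrophages was tested as an interaction with library as a block. A further term let the difference between the 2 classes vary with batch. Named genes were chosen by a rule fixed before the data were examined. In epithelial cells, macrophages and T cells it takes, of the genes passing with the same sign in every batch and library measured and a mean CPM (UMIs scaled to a common library total) of at least 20, the 12 with the largest rise and the 12 with the largest fall. In other classes it takes 3 of each, where fewer than 5 pass it takes the 5 smallest p-values, and members of the fixed lists may be named. One gene that the rule takes in epithelial cells is not reported here. Calls that fall outside that rule, such as Gcg and Lcn2 in macrophages, were named after their values were seen. Genes of which another class held more than 10 times the CPM were counted as open to free RNA, RNA released into the suspension and captured in any droplet.

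The gene test was checked on simulated counts with 200 changed genes, 100 at each log2 size, drawn at the trend of the dispersion and at each gene's own dispersion. False shares depend on how many genes change, so they do not carry over to the real calls, which were far more in epithelial cells. The dispersions were those of these libraries, so the check does not cover how far a lone placebo tumour may differ from others. In the epithelial comparison, with 16389 genes, the test recovered 73% of genes changed by a log2 of 1 and 93% of those changed by 2, and 6.74% of calls were false. At each gene's own dispersion these were 69%, 93% and 28.6%. In the macrophage comparison (11810 genes) the values were 48%, 85% and 4.32% at the trend and 39%, 80% and 27.4% at each gene's own dispersion. In the T cell comparison (6928 genes) they were 12%, 64% and 0% at the trend, and 19%, 73% and 21.4% at each gene's own dispersion.

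Alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, its size factors within edgeR, no filter on low counts, no batch term, the progesterone libraries of batch 2 summed, each library left out, doublets kept, a minimum of 500 genes, each library clustered on its own, Leiden resolution 2, UMIs thinned to the lowest library of a class, genes open to free RNA left out, and the estimated correlation. Chosen after the data were examined were the minimum of 10 cells, batch 2 alone, clusters named with no rule on depth, the removal of the keratin-led sub-cluster, and a limit of 2 in place of 3 markers of another class. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used for the other steps. Progesterone 2 and Progesterone 3 were checked for double deposition and differed by more than counting noise (chi-square per degree of freedom 122 over 15669 genes, log2 CPM correlation across genes 0.997).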

Results

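Transcripts of single cells were counted in 5 libraries from SSM2 mammary tumours, 2 from mice with placebo pellets and 3 from mice with pellets releasing progesterone, the steroid hormone that acts through the progesterone receptor. Batch 1 held Placebo 1 (43194597 UMIs over 4940 barcodes) and Progesterone 1 (23409215 UMIs over 2241 barcodes). Batch 2 held Placebo 2 (197264441 UMIs, 5857 barcodes), Progesterone 2 (204786073 UMIs, 5514 barcodes) and Progesterone 3 (182845008 UMIs, 5470 barcodes). The median barcode held 8212 and 6172 UMIs in the libraries of batch 1, in that order, and 23702, 24663 and 25316 in those of batch 2. After removal of doublets and barcodes with few genes, 4744, 2191, 5583, 5271 and 5229 cells remained in the order Placebo 1, Progesterone 1, Placebo 2, Progesterone 2 and Progesterone 3. The title of the series poses the question of how progesterone alters the immune cells of these tumours. Classes named below rest on marker genes, and each is meant as "T cell-like", "macrophage-like" and so on.

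The libraries differed widely in makeup. T cells made up 92.5% of haematopoietic cells in Placebo 1 (95% exact interval 91.7 to 93.3%) and 28.6% in Progesterone 1 (26.2 to 31%), against 8.52% in Placebo 2 (6.78 to 10.5%), 2.29% in Progesterone 2 (1.5 to 3.33%) and 6.99% in Progesterone 3 (5.29 to 9.02%). Macrophages made up 0.371% in Placebo 1 (0.212 to 0.602%) and 19.9% in Progesterone 1 (17.8 to 22.1%), and 68.3% in Placebo 2 (65.1 to 71.3%), 82.4% in Progesterone 2 (80.1 to 84.6%) and 72.7% in Progesterone 3 (69.4 to 75.8%). Neutrophils made up 0.139% in Placebo 1 (0.0511 to 0.303%) and 23.4% in Progesterone 1 (21.2 to 25.7%), and 0.442% in Placebo 2 (0.121 to 1.13%), 2.29% in Progesterone 2 (1.5 to 3.33%) and 3.75% in Progesterone 3 (2.53 to 5.34%). The neutrophil share was thus higher with progesterone in all 3 progesterone libraries, but the difference did not pass the test (log2 ratio 4.47, SE 2.24, edgeR adjusted p = 0.461). Epithelial cells, the tumour cells among them, were 0.0231% of named cells in Placebo 1 (1 cell), 3.85% in Progesterone 1 (59 cells), and 67.6%, 71.0% and 77.6% in Placebo 2, Progesterone 2 and Progesterone 3.

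No class passed in the test of shares between treatments. With batch as a covariate the log2 ratios of haematopoietic shares, progesterone over placebo, were 1.90 for macrophages (SE 2.03), -1.24 for T cells (SE 1.75), -1.52 for B cells (SE 2.04), -2.24 for NK cells (SE 2.20), 1.39 for conventional dendritic cells (SE 1.85) and 1.08 for plasmacytoid dendritic cells (SE 1.85), each with an edgeR adjusted p = 0.569. None of the 7 classes had an unadjusted p under 0.05, the lowest being 0.0659 for neutrophils. Without Placebo 2 the log2 ratios were 5.72 for macrophages and 7.33 for neutrophils, in a fit that sets Placebo 1 against Progesterone 1 alone. Over all named cells the lowest adjusted p was 0.665, and over T and NK cell sub-classes all were 0.899. Within batch 2 alone the macrophage share was higher and the T cell share lower in both progesterone libraries than in Placebo 2, but for both classes the intervals of Placebo 2 and Progesterone 3 overlapped. B cells made up 6.19% of haematopoietic cells in Placebo 2, 1.23% in Progesterone 2 and 0 of 773 cells in Progesterone 3, which allows a share of up to 0.388%. The order was the opposite in batch 1, with 3.78% in Placebo 1 and 15.2% in Progesterone 1.

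**Figure D1:**
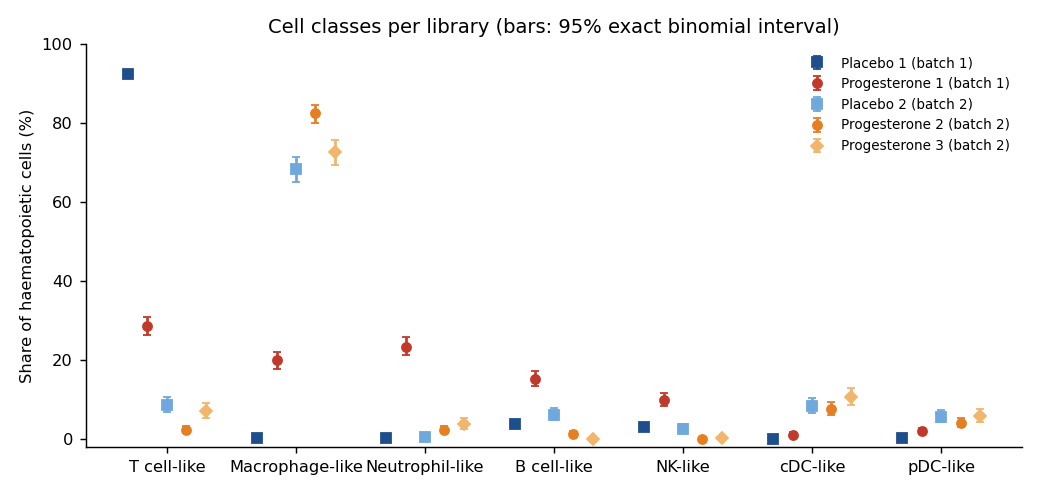
Share of each class among haematopoietic cells (y axis, percent) in each library, with placebo as squares, progesterone as circles and diamonds, and bars for the 95% exact binomial interval, which covers counting error only. Placebo 1 stands apart with 92.5% T cells, and macrophages lie between 68.3% and 82.4% in the 3 libraries of batch 2.

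Some genes nearly absent from epithelial cells of Placebo 2 were high in those of the progesterone tumours. Calca (calcitonin and its related peptide, chromosome 7 from 114631478 to 114636357, minus strand) had 4 UMIs in Placebo 2, against 1549, 21315 and 15130 in Progesterone 1, 2 and 3, a log2 rise of 11.25 (SE 0.38, adjusted p = 2.73e-06). Muc19, a gel-forming mucin gene (chromosome 15, 91838326 to 91934555, plus strand), rose by a log2 of 10.97, and Defb1, a defensin gene, by 8.66. Smgc, a submandibular gland gene, had 1 UMI in Placebo 2 and rose to a CPM ratio of 9500 (counting interval 1705 to 375260). Krt17, a keratin of basal and stressed epithelium (chromosome 11, 100256217 to 100261029, minus strand), fell by 5.83 on the log2 scale, and Aldh1a1, a retinaldehyde dehydrogenase gene, fell by 7.84. Lcn2, which encodes a siderophore-binding protein, fell by 3.06, from 1187 CPM in Placebo 2 to 142 in Progesterone 2, 143 in Progesterone 3 and 249 in Progesterone 1. The transcription factor Zbtb16, a known steroid receptor target, rose by 4.08, Igfbp5 by 4.12, and Kitl, the ligand of the Kit receptor, by 4.13.

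The fixed rule also named Tfap2b, Fam25c, Agtr1a and Ppic, which rose by log2 values from 4.32 (Ppic) to 5.16 (Tfap2b). Among those lower were Defb45, Ifitm1, Fmo2, Timp1, Srgn, Fgb, Fam20a, Bpifa1 and Barx2, with log2 ratios from -8.69 (Defb45) to -2.90 (Barx2). For Ppic, Ifitm1, Timp1 and Srgn another class held 12.8, 14.6, 88.7 and 155 times the epithelial CPM, so free RNA is open for them. Different clusters held the class in the 2 groups. Cluster 0, led by Krt15, Calca, Muc19 and Defb1, had 49 cells of Placebo 2 against 1549 and 1572 of Progesterone 2 and Progesterone 3. Cluster 2, led by Dcpp1, Gcg, Fmo2 and Krt17, had 2256 cells of Placebo 2 against 7 and 2. In epithelial cells 8119 of 16389 genes passed, 3990 higher and 4129 lower with progesterone, against 4377 by DESeq2, 2784 with UMIs thinned to the lowest total and 2641 with no depth rule for cluster names. Of these 1315 (16.2%) had over 10 times the CPM in another class. These tests set 1 placebo library against the 2 progesterone libraries of batch 2, which may come from 1 animal, so they do not separate progesterone from a difference between single tumours. With no replicate block, which brings in Progesterone 1, 927 genes passed, 914 of them among the 8119. Of the 23 genes given here by the rule 21 then passed, all but Fam25c (adjusted p = 0.0675) and Srgn (0.0767).

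**Figure D2:**
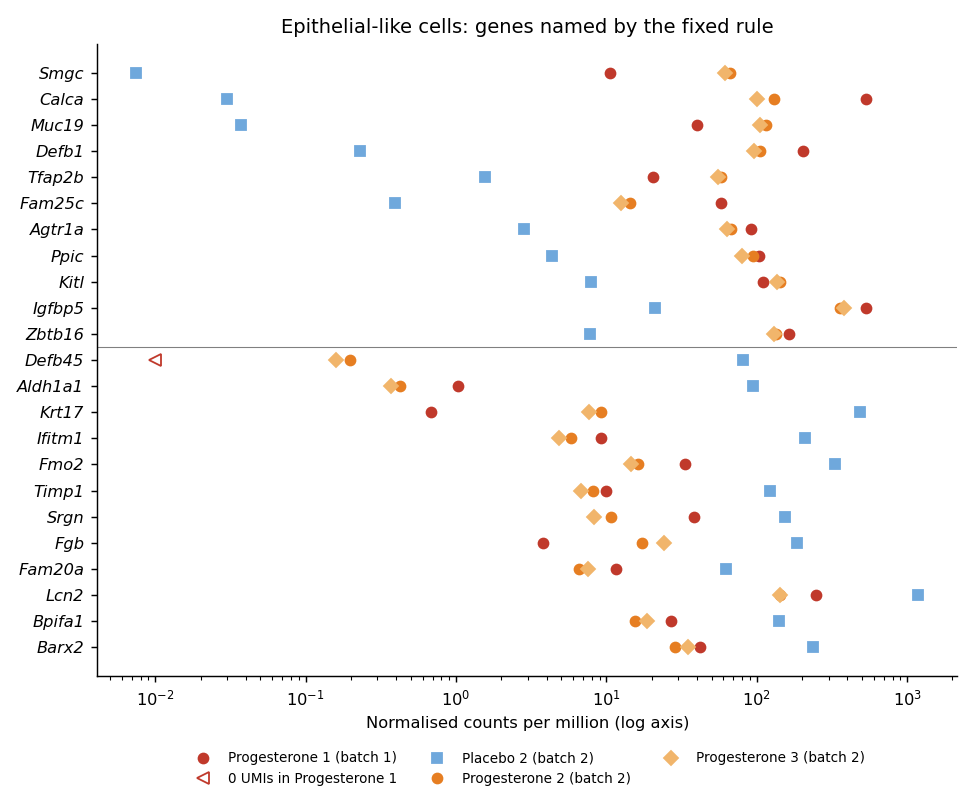
Normalised counts per library (x axis, CPM, log scale) of 23 genes that the fixed rule named in epithelial cells, higher with progesterone above the line and lower below it. Each of the 3 progesterone libraries lies on the same side of Placebo 2 for every gene drawn, such as Calca at 0.0298 CPM in Placebo 2 and 99.8 CPM or more with progesterone.

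MHC class I and cholesterol synthesis genes were lower in epithelial cells with progesterone. Of the 16 genes of MHC class I presentation, which display peptides to CD8 T cells, 14 fell, none rose and 2 did not pass (14 adjusted over the list alone, median log2 ratio -0.90). Among them were H2-K1 (-1.85), H2-D1 (-1.72), the peptide transporter gene Tap1 (-1.68) and the proteasome subunit gene Psmb8 (-1.63). The list passed (camera adjusted p = 1.37e-10, adjusted p = 0.532 with an estimated correlation). Of 17 cholesterol synthesis genes 16 fell and 1 did not pass (16 adjusted over the list alone, median -0.86), including Cyp51 (-1.47), Fdps (-1.19) and Sqle (-1.12). That list had a camera adjusted p = 4.31e-09, and adjusted p = 0.532 with an estimated correlation. Of 19 hypoxia and glycolysis genes 15 fell, 2 rose and 2 did not pass (17 adjusted over the list alone, median -0.62). The glycolytic genes Pgk1 (-1.33), Ldha (-0.88) and Aldoa (-0.78) fell, and Vegfa, a growth factor gene for blood vessels, rose (0.34). The camera adjusted p = 6.78e-05 for this list became adjusted p = 0.532 with an estimated correlation. Of 7 milk and alveolar genes 5 fell and 2 did not pass (5 adjusted over the list alone, median -2.53), with Lcn2, Wfdc18 (-2.53) and the folate receptor gene Folr1 (-4.38) among them. Its camera adjusted p = 1.37e-10 likewise became adjusted p = 0.532 with an estimated correlation. Wfdc18 stood at 135 CPM in Progesterone 1, above the 42.5 CPM of Placebo 2, and its log2 ratio was 0.025 with no replicate block. Cluster 27, led by Wfdc18, Csn3 and Ltf, held 34 of the 2793 epithelial cells of Placebo 2, 10 of 2976 in Progesterone 2, 7 of 3206 in Progesterone 3 and 10 of 59 in Progesterone 1.

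Mitotic genes were higher in epithelial cells with progesterone. Of 24 G2M genes 17 rose, 1 fell and 6 did not pass (19 adjusted over the list alone, median 0.66), with Aurka (0.98), Kif20b (1.12) and Tpx2 (0.94) among those that rose and Cdk1 (-0.52) the one that fell. The list passed (camera adjusted p = 0.00115, adjusted p = 0.794 with an estimated correlation), but had adjusted p = 0.0572 with no replicate block. Of 17 extracellular matrix genes 16 fell and 1 did not pass (16 adjusted over the list alone, median -1.60), Fn1, the fibronectin gene, among them (-2.19). The camera adjusted p = 1.74e-07 of this list went to adjusted p = 0.532 with an estimated correlation. For all 17 another class held more than 10 times the CPM, and fibroblast marker genes had 28.4 CPM in epithelial cells of Placebo 2 against 8.24, 10.7 and 12.2 in Progesterone 1, 2 and 3. Of 29 interferon-stimulated genes 15 fell, 5 rose and 9 did not pass (22 adjusted over the list alone, median -0.54), such as Isg15 (-1.27), Bst2 (-0.87) and Irf1 (0.77), and 17 of the 29 were over the same ratio. This list passed too (camera adjusted p = 0.00743, adjusted p = 0.532 with an estimated correlation). Of 11 basal and mesenchymal genes 6 fell, 2 rose and 3 did not pass (8 adjusted over the list alone, median -0.75). They passed as a list (camera adjusted p = 0.00172, adjusted p = 0.532 with an estimated correlation and 0.286 with no replicate block), and 6 of the 11 were over that ratio. Of 16 unfolded protein response genes 11 fell, 2 rose and 3 did not pass (13 adjusted over the list alone, median -0.47), and the stress-induced genes Manf (-0.76) and Ddit3 (0.81) went opposite ways. The list passed downwards (camera adjusted p = 0.0147, adjusted p = 0.532 with an estimated correlation).

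Lists tied to the hormone did not pass camera in epithelial cells. For change in either direction, fry asks only whether members of a list change. With so many genes called in this class, such a call is not particular to a list. Fry passed 13 of the 17 epithelial lists as change in either direction, among them progesterone-responsive genes (adjusted p = 0.0274) and steroid receptor targets (0.0286), and none in 1 direction (lowest adjusted p = 0.087). Of 13 progesterone-responsive mammary genes 3 rose, 6 fell and 4 did not pass (10 adjusted over the list alone, camera adjusted p = 0.554). Calca and Wnt4 (0.90), a Wnt ligand gene, were among the higher ones, and Areg (-1.56), an epidermal growth factor receptor ligand gene, and Pgr (-0.40), the receptor gene itself, among the lower. Median and mean of that list differed in sign (-0.40 and 0.57), with the test up. Pgr stood at 400 CPM in Progesterone 1 and 247 in Placebo 2, and its log2 ratio was 0.052 with no replicate block. Of 11 shared steroid receptor targets 5 rose, 3 fell and 3 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0926). Fkbp5 (1.44) was among the former and the metallothionein genes Mt1 (-1.36) and Mt2 (-1.58) among the latter. Of 11 estrogen-responsive and luminal genes 4 rose, 2 fell and 5 did not pass (6 adjusted over the list alone, camera adjusted p = 0.554), including Esr1, the estrogen receptor gene (0.82), and Foxa1 (-0.51). Its median was -0.02, its mean 0.37 and its test up. Of 22 S phase genes none rose and 7 fell (6 adjusted over the list alone, adjusted p = 0.0926), and of 8 MHC class II genes 1 fell (0 adjusted over the list alone, adjusted p = 0.739). Of 20 myeloid-recruiting chemokines and growth factors 1 rose and 8 fell (9 adjusted over the list alone, adjusted p = 0.0601), and of 15 checkpoint ligands and suppressive enzymes 1 rose and 7 fell (8 adjusted over the list alone, adjusted p = 0.074). Of 19 dissociation stress genes 8 rose and 4 fell (12 adjusted over the list alone, adjusted p = 0.554), with a median of -0.01, a mean of 0.03 and a test up. The rest of these 5 lists did not pass.

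**Figure D3:**
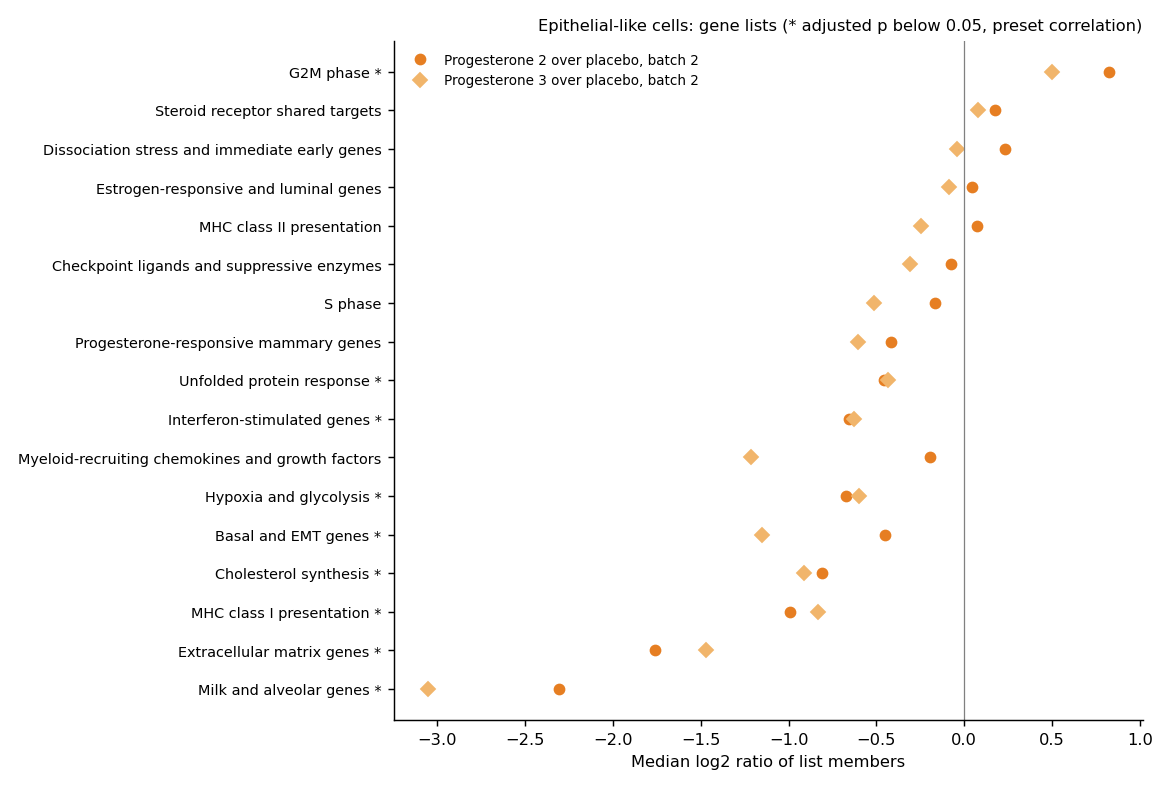
Median log2 ratio of each gene list in epithelial cells (x axis), for Progesterone 2 (circles) and Progesterone 3 (diamonds) over Placebo 2, with an asterisk for lists that passed at the preset correlation of 0.01. Medians of MHC class I genes lay at -0.99 and -0.84, and those of milk genes at -2.31 and -3.05. No asterisk remained with an estimated correlation, a test that 1 residual degree of freedom left with little power.

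The macrophage class, which may hold monocyte-like cells, had lower transcripts of monocyte genes with progesterone in both batches. Ly6c2, the gene of an antigen of inflammatory monocytes (chromosome 15, 75108158 to 75111970, minus strand), fell by 2.61 on the log2 scale (SE 0.22, adjusted p = 0.0113), from 1500 to 206 CPM in batch 1 and from 62.0 to 12.8 and 9.96 CPM in batch 2. Ccl7, a chemokine that draws monocytes, fell by 2.36 (SE 0.22, adjusted p = 0.0199), from 611 to 155 CPM in batch 1 and from 1337 to 238 and 193 CPM in batch 2. Ly6a (-1.95, adjusted p = 0.0486), Dmkn (-2.78, adjusted p = 0.0113), Gcg (-6.41, adjusted p = 0.000608) and Lcn2 (-2.22, adjusted p = 0.0486) completed the 6 genes of 11810 that passed, all lower. For 5 of the 6, all but Ccl7, another class held over 10 times the CPM, which for Gcg, Lcn2 and Dmkn was 16.5, 43.0 and 15 times. Dmkn turned higher with each library clustered on its own, and Lcn2 lost its call without Progesterone 2 or Progesterone 3. Epithelial cells held Gcg at 857 CPM in Placebo 2 and at 0.908 CPM in Progesterone 2. Ccl2 (-2.01, adjusted p = 0.0907) and Spp1, the osteopontin gene (2.18, adjusted p = 0.0907), had the same sign in all 3 comparisons within batches but did not pass.

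The count rests on few cells and on both batches. Placebo 1 held 16 macrophages, and in batch 2 alone 2046 genes passed, 909 higher and 1137 lower, the 6 genes among them. Leaving out 1 library gave 2102 genes without Placebo 1, 1906 without Progesterone 1 and 1715 without Placebo 2, with 6, 6 and 5 of the 6 genes among them, and 14 and 20 without Progesterone 2 and Progesterone 3. With the batch term, fits without Placebo 1 or Progesterone 1 repeat the comparison within batch 2. The fit without Placebo 2 sets Placebo 1 against Progesterone 1 alone. With no replicate block 0 passed in edgeR, against 159 by DESeq2 with the block and 1612 genes at an unadjusted p under 0.05. Log2 ratios of batch 1 and batch 2 correlated at 0.0948 across genes, which are not independent replicates, and 56.3% of genes had the same sign. Different clusters led in the libraries. Cluster 3, led by Apoe, Trem2 and C1q genes, held 3, 161, 234, 756 and 445 cells in the order Placebo 1, Progesterone 1, Placebo 2, Progesterone 2 and Progesterone 3, and cluster 9, led by Retnla, Mrc1, F13a1 and Ccl7, held 12, 117, 380, 145 and 98. Cluster 9 scored 5.45 for macrophage and 4.09 for monocyte markers, against 6.28 and 1.93 in cluster 3. Lower monocyte genes thus cannot be told apart from fewer cells of cluster 9 in the class. With each library clustered on its own, only Progesterone 1 (206 cells) and Placebo 2 (61 cells) had a cluster named monocytes. Tumour keratin and Epcam transcripts, a measure of free RNA, stood at 7.11 and 60.8 CPM in macrophages of batch 1 and 990, 668 and 572 CPM in those of batch 2.

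Monocyte-derived genes were lower as a set in macrophages. Of 12 such genes 2 fell, none rose and 10 did not pass (8 adjusted over the list alone), with medians of -0.63 in batch 1 and -1.13 for both Progesterone 2 and Progesterone 3. This list passed with camera and with fry (camera adjusted p = 6.27e-14, fry adjusted p = 0.0268), and had adjusted p = 0.255 with an estimated correlation. The fry call was lost with no replicate block (adjusted p = 0.546) and in batch 2 alone (0.168), and for 6 of the 12 genes another class held over 10 times the CPM. Lipid-associated genes, a set of foam cells and tumour macrophages, had a median of 1.65 in batch 1 and of 0.53 and 0.29 in batch 2. None of the 17 passed alone (3 adjusted over the list alone), with Trem2 (1.14) and Cd9 (1.61) among the higher ones. That list passed upwards (camera adjusted p = 1.5e-06, adjusted p = 0.659 with an estimated correlation). Of 31 interferon-stimulated genes none passed alone (10 adjusted over the list alone), Irf7 had a log2 ratio of -1.40, and the medians were -0.93, -0.49 and -0.31. The list passed downwards (camera adjusted p = 2.99e-09, adjusted p = 0.656 with an estimated correlation). Checkpoint ligands and suppressive enzymes, with medians of 0.53, 0.30 and 0.31, had none of 13 genes passing (2 adjusted over the list alone). They passed upwards (camera adjusted p = 0.0308, adjusted p = 0.656 with an estimated correlation and 0.118 with no replicate block), and Cd274, the gene of PD-L1, had a log2 ratio of 1.26 and 13.7 times the CPM in another class.

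Of the other lists that passed in macrophages all but the chemokine list had medians more than 1 apart between the batches. In batch 2 alone steroid targets, G2M, interferon-stimulated and lipid-associated genes did not pass (camera adjusted p = 0.687, 0.971, 0.554 and 0.169). The S phase list had a median of -2.06 in batch 1 and of -0.34 and -0.66 in batch 2, and the G2M list of -4.26, -0.03 and -0.23. No gene of the 22 and 24 passed, and 0 adjusted over the list alone in each. Both passed downwards, S phase with a camera adjusted p = 2.99e-09 (adjusted p = 0.656 with an estimated correlation) and G2M with 4.68e-07 (adjusted p = 0.659 with an estimated correlation). Cluster 28, with Mki67 and Hist1h1b among its leading genes, held 1 of 16 macrophages in Placebo 1 and 0 of 278 in Progesterone 1. In batch 2 it went the other way, with 3 of 617 in Placebo 2, 36 of 937 in Progesterone 2 and 19 of 562 in Progesterone 3. Steroid receptor targets had medians of 1.34, 0.17 and -0.12, none of 11 passing alone (2 adjusted over the list alone) and Sgk1, a glucocorticoid-induced kinase gene, at a log2 ratio of 1.06. They passed upwards (camera adjusted p = 0.00519, adjusted p = 0.659 with an estimated correlation). Of 15 myeloid-recruiting chemokines and growth factors Ccl7 fell and 14 did not pass (5 adjusted over the list alone, medians 0.13, -0.02 and -0.62). The list passed downwards (camera adjusted p = 0.0276, adjusted p = 0.659 with an estimated correlation). Cholesterol synthesis genes had medians of 0.75 in batch 1 and -1.06 for both libraries of batch 2, with Idi1 at -1.98 and Cyp51 at -1.26. None of the 17 passed alone (5 adjusted over the list alone), the list passed downwards (camera adjusted p = 8.47e-06, adjusted p = 0.659 with an estimated correlation), and 15 fell in batch 2 alone.

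Tissue-resident macrophage genes had opposite signs in the batches and did not pass (camera adjusted p = 0.522). None of the 14 rose or fell (0 adjusted over the list alone), and the fitted median was -0.92. Lyve1, a hyaluronan receptor gene of resident macrophages (chromosome 7, 110850607 to 110863239, minus strand), stood at 156 CPM in Placebo 2, 2.17 in Progesterone 2 and 2.18 in Progesterone 3. It stood at 0 CPM in Placebo 1 and 7.76 in Progesterone 1, did not pass (adjusted p = 0.291) and had 19.4 times the CPM in another class. Cd163, a haemoglobin scavenger receptor gene, stood at 152 CPM in Placebo 2 against 6.22 and 8.05 in Progesterone 2 and Progesterone 3, and at 0 CPM in Placebo 1 and 8.46 in Progesterone 1 (adjusted p = 0.291). Over batch 2 alone 10 of 15 tissue-resident genes fell and 1 rose (median -1.75, camera adjusted p = 4e-48, adjusted p = 0.495 with an estimated correlation). No gene passed in 8 further lists that did not pass either. They were the M2-like list (20 genes, 3 adjusted over the list alone, adjusted p = 0.934), the M1-like list (18, 2 adjusted over the list alone, 0.425), and complement and efferocytosis genes (15, 9 adjusted over the list alone, 0.522, with a median of 0.23, a mean of -0.07 and a test up). The others, each with 0 adjusted over the list alone, were MHC class I (16, 0.0897), MHC class II (10, 0.522), hypoxia and glycolysis (19, 0.209), the unfolded protein response (15, 0.675) and dissociation stress (19, 0.522). In batch 2 alone the M2-like list passed downwards (9 of 20 fell, 3 rose, camera adjusted p = 8.31e-09), as did hypoxia and glycolysis (4 of 19 fell, 0.00757). The M1-like list passed upwards there (5 of 18 rose, 1 fell, 0.018), and each of the 3 had adjusted p = 0.495 with an estimated correlation.

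**Figure D4:**
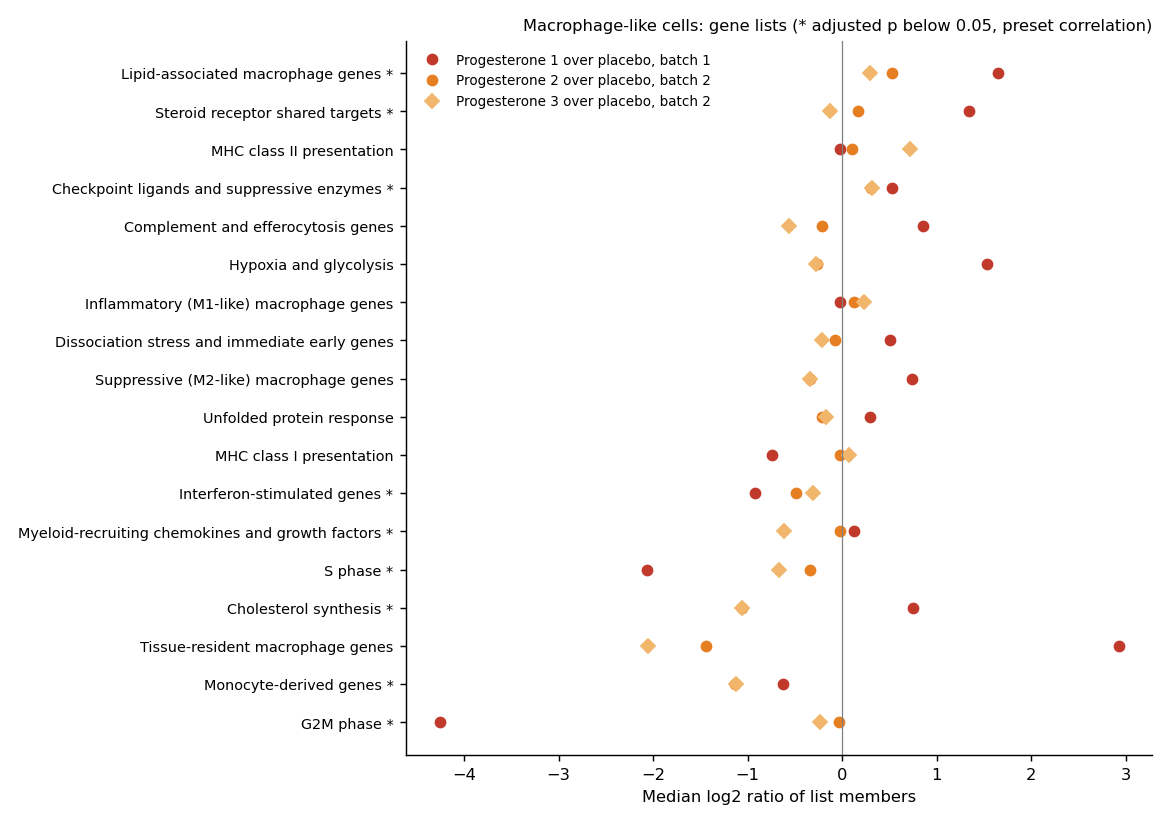
Median log2 ratio of each gene list in macrophages (x axis), progesterone over the placebo library of the same batch, for Progesterone 1, Progesterone 2 and Progesterone 3, with an asterisk for lists that passed at the preset correlation of 0.01. Monocyte-derived genes lay at -0.63, -1.13 and -1.13, and tissue-resident genes at 2.93 in batch 1 but -1.44 and -2.06 in batch 2. The size of the 2.93 may depend on the prior count, as members such as Lyve1 and Cd163 had 0 UMIs in Placebo 1.

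In T cells 1 gene of 6928 passed, Calca, which was higher with progesterone in both batches. It had 6 UMIs in 3990 T cells of Placebo 1 and 203 in 399 of Progesterone 1, and 0 in 77 of Placebo 2 against 6 in 26 of Progesterone 2 and 9 in 54 of Progesterone 3 (log2 ratio 6.72, SE 0.60, adjusted p = 0.0107). Another class held 14.4 times the Calca CPM of T cells, and 120 of the 203 UMIs in Progesterone 1 came from 1 cell. The next genes by p-value, Hgsnat (2.03), Fam171b (2.58), Irf8 (1.88) and Krt15 (3.68), did not pass (adjusted p = 0.542 each), and Irf8 and Krt15 were 124 and 326 times higher in another class. At an unadjusted p under 0.05 there were 352 genes, DESeq2 called 14, and with no replicate block 0 passed in edgeR (Calca 6.40, adjusted p = 0.106). In batch 2 alone the Calca log2 ratio was 2.72 (adjusted p = 0.903). Without Placebo 2 the fit sets Placebo 1 against Progesterone 1 alone, and its count of calls does not bear on both batches.

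Gene lists of T cell state lay higher with progesterone in batch 1, where the libraries also differed widely in T cell sub-clusters (below). The exhaustion list had medians of 1.73, 0.02 and 0.20 in Progesterone 1, 2 and 3 over the placebo of their batch. The cytotoxic and effector list had 2.80, 0.12 and -0.01, and the regulatory T cell list 1.61, 0.07 and 0.15. For 8 of the 11 cytotoxic genes another class held over 10 times the CPM. None of their 10, 11 and 11 genes passed, with 0 adjusted over the list alone. The lists passed upwards, with camera adjusted p-values of 0.000182, 2.08e-05 and 1.46e-05, and each had adjusted p = 0.442 with an estimated correlation. The G2M list (medians 2.37, 0.68 and 0.09, none of 15 passing, 4 adjusted over the list alone) and the dissociation stress list (medians 0.59, 0.58 and -0.01, none of 19 passing, 4 adjusted over the list alone) also passed upwards. Their camera adjusted p-values were 5.13e-08 and 3.95e-06, and both had adjusted p = 0.442 with an estimated correlation. None of these 5 lists passed without Placebo 1 or without Progesterone 1. In batch 2 alone camera adjusted p-values were 0.29 (exhaustion), 0.924 (cytotoxic, test down), 0.348 (regulatory), 0.196 (G2M) and 0.113 (stress). Members that did not pass included Pdcd1, the gene of the PD-1 receptor (1.62), the chemokine gene Xcl1 (2.94, 55.7 times the CPM in another class), Ikzf2 (1.17), Top2a (1.56) and Hspa1a, a heat shock protein gene (2.88). Of 10 naive and memory genes none passed (medians -0.98, 0.84 and -0.54, 1 adjusted over the list alone, camera adjusted p = 0.478). With 0 adjusted over the list alone, steroid targets (10 genes, 0.156), S phase (15, 0.554), MHC class I (15, 0.602) and interferon-stimulated genes (14, 0.666) did not pass.

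Different sub-clusters held the T cells of the libraries. Sub-clusters 0, 1 and 2, the largest, had 904, 839 and 818 cells of Placebo 1 against 9, 33 and 10 of Progesterone 1. None of their cells came from batch 2. Sums over the class thus do not separate a change within T cells from a change of makeup. In the order Placebo 1, Progesterone 1, Placebo 2, Progesterone 2 and Progesterone 3, sub-cluster 4 (led by Tnfsf8, Esm1, Il1rl1 and Calca) had 257, 124, 13, 2 and 8 cells. Sub-cluster 7 (S100a9, S100a8, Camp and Mki67) had 26, 39, 53, 21 and 44, so most cells kept as T cells in batch 2 were in it. The neutrophil genes S100a9, S100a8, Camp and Ngp were among its 10 leading genes, though T cells of batch 2 had 0 UMIs of the first 2. By the fixed markers it scored as regulatory T cells (score 6.12, against 5.93 in the sub-cluster so named). Only S100a9 and S100a8 were fixed markers of another class, so the sub-cluster got no sub-class name but stayed in the class, as removal needed 3. Without it Progesterone 2 had fewer than 10 T cells, and a fit of the other 4 libraries called 41 of 8861 genes (33 higher, 8 lower), Calca among them (7.39), and Pdcd1 (2.42), Xcl1 (2.74) and Krt15 (4.40) newly passed. The 5 lists passed in that fit too, G2M and stress with a camera adjusted p = 0.0451 each. Sub-cluster 10 (Hspa1b) had 72 of its cells in Progesterone 1. The neutrophil transcripts S100a8 and S100a9 together had 13.4 CPM in T cells of Placebo 1, 1748 in Progesterone 1 and 0 in batch 2. Tumour keratin and Epcam transcripts had 5.81, 66.0, 904, 1408 and 928 CPM in T cells, in the order given.

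**Figure D5:**
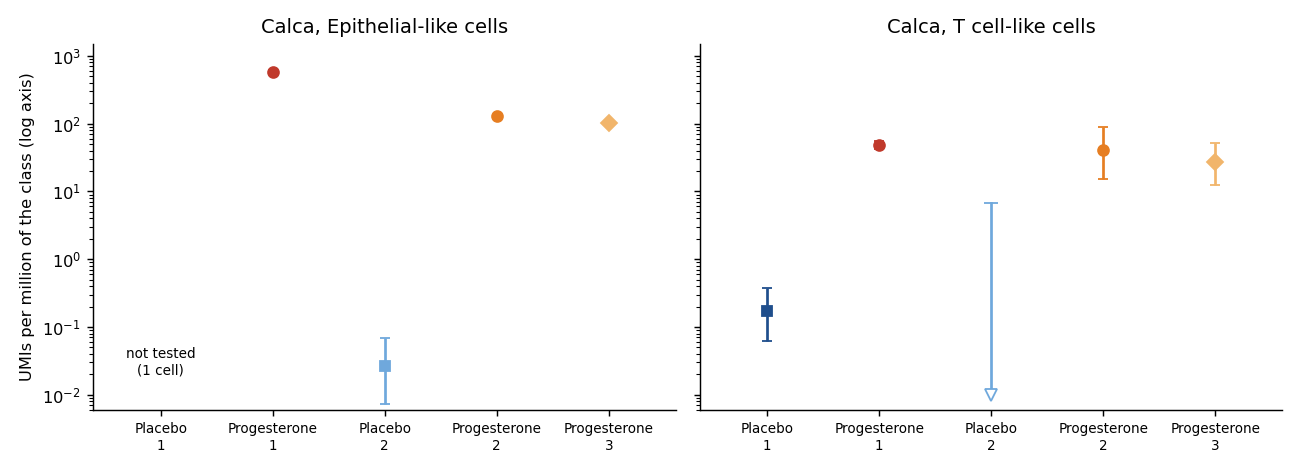
Calca UMIs per library in epithelial cells (left) and T cells (right) as CPM on a log axis, with 95% exact Poisson intervals for counting error; the open triangle marks 0 UMIs with its upper limit of 6.73 CPM. T cells lay at 0.172 CPM in Placebo 1 and between 27.1 and 48.4 CPM in the progesterone libraries.

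Fibroblasts of the progesterone tumours of batch 2 showed higher mitotic genes than those of Placebo 2. Of 24 G2M genes 19 rose, none fell and 5 did not pass (23 adjusted over the list alone, median 2.01), among them Ube2c (3.33), Ccnb1, the gene of cyclin B1 (2.83), and Top2a (1.88). The list had a camera adjusted p = 5.01e-39 and adjusted p = 0.259 with an estimated correlation. Of 15 myeloid-recruiting chemokines and growth factors 5 rose, 2 fell and 8 did not pass (10 adjusted over the list alone), with Cxcl1, a neutrophil attractant gene (1.76), Ccl7 (1.46), Cxcl14 (1.22) and Il34 (-1.02). The list passed upwards (camera adjusted p = 0.000609, adjusted p = 0.259 with an estimated correlation). Of 19 hypoxia and glycolysis genes 5 rose (6 adjusted over the list alone), Vegfa (0.92) and Ndrg1 (1.36) among them. Of 17 extracellular matrix genes 4 rose (9 adjusted over the list alone), which were Tnc (1.02), Lox (0.89), Bgn (0.85) and Thbs2 (0.75). None of either list fell, and they passed upwards with camera adjusted p-values of 1.1e-06 and 0.000609 (adjusted p = 0.259 with an estimated correlation for both). With no replicate block the matrix (adjusted p = 0.369, test down), hypoxia (0.0535) and chemokine (0.218) lists did not pass. Progesterone 1 stood below Placebo 2 for Tnc (90.7 against 1772 CPM), Lox (239 against 549), Thbs2 (89.5 against 645), Vegfa (66.8 against 172), Ndrg1 (87.1 against 119) and Ube2c (8.35 against 12.5), and level with it for Ccnb1 (3.58 in both).

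Further lists passed upwards in fibroblasts, with no member falling. Of 19 dissociation stress genes 4 rose (8 adjusted over the list alone), of 14 MHC class I genes 2 rose (3 adjusted over the list alone), and of 7 MHC class II genes 3 rose (3 adjusted over the list alone). Camera adjusted p-values were 6.47e-07, 0.000829 and 1.47e-08 in that order, and each had adjusted p = 0.259 with an estimated correlation. All 7 MHC class II genes had over 10 times the CPM in another class. Macrophage markers stood at 28.3 CPM in fibroblasts of Placebo 2 and at 21.2, 85.7 and 73.5 in those of Progesterone 1, 2 and 3. Of 22 S phase genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.00435, adjusted p = 0.618 with an estimated correlation). No gene passed among 11 steroid targets (1 adjusted over the list alone, adjusted p = 0.122) and 25 interferon-stimulated genes (0 adjusted over the list alone, adjusted p = 0.374), and these lists did not pass.

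By the fixed rule Tuft1 (3.98), Il1b (3.75) and Ube2c rose most in fibroblasts, Il1b with 244 times the CPM in another class, and Rgs5, a pericyte gene, Zfp804b and the B cell chemokine gene Cxcl13 fell most. Rgs5 stood at 34.9 CPM in Placebo 2 and 1.22 and 0.357 in the progesterone libraries of batch 2, but at 384 in Progesterone 1, and Zfp804b (9.40 against 0.609 and 0, and 205) and Cxcl13 (6.38 against 0 and 0, and 208) had the same split. In all 492 of 11573 genes passed (286 higher, 206 lower), 71 of them with over 10 times the CPM in another class. With no replicate block 0 passed in edgeR, against 91 by DESeq2 with the block and 1681 genes at an unadjusted p under 0.05. Without the block Rgs5, Zfp804b and Cxcl13 had log2 ratios of 1.83, 2.73 and 3.26.

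Dendritic cells and B cells gave shorter sets. In plasmacytoid dendritic cells 148 of 7500 genes passed (52 higher, 96 lower, 22 with no replicate block), against 4 by DESeq2, 41 with no filter on low counts and 0 with each library clustered on its own. Ifi44 (-3.16), Isg15 (-2.87) and Irf7 (-1.64) were among the lower ones, although Ifi44 in Progesterone 1, at 98.0 CPM, was close to the 103 CPM of Placebo 2. Tram2 (2.68), Alkal1 (2.50) and Krt15 rose most there, Krt15 from 2 placebo UMIs at a CPM ratio of 18.6 (counting interval 4.91 to 157) and with 32.6 times the CPM in another class. Cyp7b1 (-4.02), Ccl3 (-3.70, 117 times the CPM in another class) and Ifitm1 (34.4 times) fell most, Ifitm1 to 2 progesterone UMIs (ratio 0.00988, interval 0.000246 to 0.057). In conventional dendritic cells 7 of 9217 genes passed, with Tex14 (2.40) and Ifitm1 (2.31) higher and Cxcl10, an interferon-induced chemokine gene (-3.50), Asgr2 (-2.93), Cd36 (-2.37, 13.1 times the CPM in another class) and Ccl22 (-2.21) lower, and 0 passed with no replicate block (870 genes at an unadjusted p under 0.05 with the block, 2 by DESeq2). In B cells of Placebo 1, Progesterone 1, Placebo 2 and Progesterone 2, with 14 cells in the last, 21 of 7481 genes passed. The heat shock genes Hspa1a (2 placebo UMIs, CPM ratio 120, interval 33.0 to 997) and Hspa1b (4.33) and S100a4 (4.01, 12.5 times the CPM in another class) rose most, and Sntb1 (-3.87, 36.0 times), Slc2a13 (-3.74) and Tmem108 (-2.51) fell most. T cell markers in these B cells went from 46.8 to 6.37 CPM in batch 1 and from 16.7 to 0 in batch 2.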

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

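Both tests of the tissue-resident macrophage genes, and the fits of the interaction with no replicate block and without Progesterone 1, were chosen after the result was seen. For the interaction, no replicate block means that only the term for batch was dropped, which brings Progesterone 1 into the comparison. Library stayed as a block there.

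The progesterone effect differed between epithelial cells and macrophages for 3377 of 14499 genes in an edgeR test of the interaction, 1650 with a higher and 1727 with a lower effect in epithelial cells. The differences in log2 effect, epithelial cells minus macrophages, were 3.74 for Bcar3 (adjusted p = 3.86e-19) and 3.20 for Arg1, the arginase gene (adjusted p = 3.05e-28). They were -5.25 for Ifitm1, an interferon-induced gene (adjusted p = 3.02e-30), -3.98 for Srgn (adjusted p = 1.77e-20) and -2.76 for Gk (adjusted p = 1.04e-21). The 5 genes moved in epithelial cells, with log2 ratios of 3.32, 2.39, -5.30, -4.01 and -2.27 in that order. In macrophages of Progesterone 2 they had log2 ratios of -0.34, -0.72, -0.05, -0.04 and 0.63, and in those of Progesterone 3 of -0.47, -0.84, 0.03, 0.01 and 0.39. Placebo 1 was not in this test, so both sides of it rest on Placebo 2. In batch 1, Bcar3 (2.66), Arg1 (1.69) and Ifitm1 (-2.51) went the same way in macrophages as in epithelial cells, and over all 5 libraries none of the 5 genes passed in macrophages. The interaction gave 3320 genes without Progesterone 1 and 9 with no replicate block.

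Tissue-resident macrophage genes went opposite ways in the batches, with a median log2 ratio of 2.93 in batch 1, all 14 genes higher, and of -1.44 and -2.06 in Progesterone 2 and Progesterone 3, a difference that was not tested. Members with 0 UMIs in Placebo 1, such as Lyve1 (4.84) and Cd163 (4.96), have batch 1 ratios whose size depends on the prior count. The sum of the list rose less in batch 1 than that median. The list stood at 1143 CPM in macrophages of Placebo 1, 2094 in Progesterone 1, 5718 in Placebo 2, 2197 in Progesterone 2 and 1774 in Progesterone 3, so the placebo libraries stood farthest apart. Counting error alone as the source of the difference between the placebo libraries was tested and argued against. The 16 macrophages of Placebo 1 had 482 UMIs of the list. Of 10000 draws of 16 macrophages from Placebo 2, at the same UMI total, 0% had as few (limit 0.03%, lowest draw 613). No draws were taken from Progesterone 1, so counting error behind the rise within batch 1 was not tested. Dilution by RNA of other cells cannot be told apart. C1qa, C1qb and C1qc had a log2 ratio of -2.25 between the placebo libraries, close to the -2.32 of the list. Lyz2, Tyrobp, Fcer1g, Ctss and Cd68 had -0.15, 2.18 above the list, but were picked as abundant in every library and are shared with other myeloid cells. A macrophage class of another makeup in Placebo 1 may stay as a hypothesis, as 12 of the 16 cells lay in cluster 9, Ly6c2 stood at 1589 CPM against 61.3 in Placebo 2, and Apoe at 403 CPM against 11760.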

How the results depend on the processing

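The alternatives of batch 2 alone, no depth rule for cluster names, and both refits of the interaction were chosen after the data were examined. Causes were not tested unless stated.

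The replicate block, here the batch, carried most gene calls outside B cells, where 25 passed without it (16 shared with the 21). With no replicate block 927 genes passed in epithelial cells (914 shared with the 8119), 22 in plasmacytoid dendritic cells (all shared with the 148), and 0 in macrophages, T cells, fibroblasts and conventional dendritic cells, where edgeR with the block had 1612, 352, 1681 and 870 genes at an unadjusted p under 0.05 and DESeq2 called 159, 14, 91 and 2. The interaction fell to 9 genes and fibroblast lists from 8 to 5 (matrix, hypoxia and chemokine lists lost). In epithelial cells the G2M list, the 1 that rose, was lost (adjusted p = 0.0572), as was the basal list (0.286). Signs reversed without the block for the shares of B cells (0.14) and NK cells (0.29), for Pgr (0.052) and Wfdc18 (0.025) in epithelial cells, and for Rgs5 (1.83), Zfp804b (2.73) and Cxcl13 (3.26) in fibroblasts, where Progesterone 1 then enters the comparison. With an estimated correlation 0 lists passed in epithelial cells, macrophages, T cells and fibroblasts. With 1 or 2 residual degrees of freedom that test could hardly pass any list, so it does not decide.

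DESeq2 called 4377 genes in epithelial cells (4320 shared), 159 in macrophages, 14 in T cells, 91 in fibroblasts, 2 in conventional and 4 in plasmacytoid dendritic cells. Its size factors within edgeR gave 3 in conventional dendritic cells and 55 in B cells. With no filter on low counts 783, 133, 755, 163, 41 and 83 passed in macrophages, T cells, fibroblasts, conventional and plasmacytoid dendritic cells and B cells. Thinning to the lowest total gave 2784 in epithelial cells, 18 in macrophages, 0 in T cells and 53 in conventional dendritic cells, against 8119, 6, 1 and 7 in the main fits. These counts do not say which calls were kept. Without genes open to free RNA 0 passed in macrophages and T cells and 90 in B cells. This removed Calca and 5 of the 6 macrophage genes, and Ccl7 then had adjusted p = 0.0553. Keeping doublets gave 948, 66 and 53 in fibroblasts, conventional dendritic cells and B cells, and a minimum of 500 genes gave 778 in fibroblasts and 46 in B cells. With the batch 2 progesterone libraries summed, 55 macrophage and 2 T cell genes passed. With no depth rule for cluster names 2641 epithelial (2608 shared) and 22 macrophage genes passed.

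With each library clustered on its own 2081 macrophage genes passed, as Placebo 1 then had no macrophage cluster, and 0 in plasmacytoid dendritic cells. The log2 ratio of the conventional dendritic cell share was then -6.68, and that of Dmkn in macrophages 1.36. In batch 2 alone 2046 macrophage genes passed (all 6 shared), 22 T cell genes (0 shared) and 1 T cell list, S phase, which went down (adjusted p = 0.0182), with none of the 5 lists shared. With a limit of 2 markers of another class, which took out sub-cluster 7 and with it Progesterone 2, 41 T cell genes (1 shared, Calca) and 7 lists (5 shared) passed.

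Leaving out each library in turn gave 14 to 2102 macrophage genes, 3 to 641 T cell genes, 1 to 8 T cell lists, and 0 to 2, 0 to 6 and 0 to 3 classes whose share of haematopoietic, named, and T and NK cells differed. Macrophage genes numbered 2102 without Placebo 1, 1906 without Progesterone 1, 1715 without Placebo 2, 14 without Progesterone 2 and 20 without Progesterone 3. T cell genes numbered 27, 23, 641, 3 and 4 in that order, with Calca among them each time. T cell lists numbered 1 without Placebo 1 or Progesterone 1, down and not among the 5, and 8 without Placebo 2. In all these fits with the batch term, leaving out Placebo 2 sets Placebo 1 against Progesterone 1 alone. Leaving out Placebo 1 or Progesterone 1 repeats the comparison within batch 2. Without Placebo 2 the log2 ratios of the shares were 5.72 for macrophages and 7.33 for neutrophils. Of named cells 2 classes passed without Placebo 1 or Progesterone 1 and 6 without Placebo 2, and of T and NK cells 3 without Placebo 2. The share of plasmacytoid dendritic cells reversed without Placebo 1 or Progesterone 1 (log2 ratios from -0.20 to 3.34). Without Placebo 2 those of B cells (-3.21 to 2.01) and NK cells (-4.50 to 1.73) reversed, as did Lyve1 (-6.02 to 4.70), Cd163 (-4.40 to 4.82) and Mrc1 (-2.25 to 0.45) in macrophages, the highest value being that without Placebo 2. Lcn2 in macrophages lost its call without Progesterone 2 (adjusted p = 0.0552) or Progesterone 3 (0.0678). Without Progesterone 1, 8059 epithelial, 537 fibroblast, 7 conventional and 142 plasmacytoid dendritic cell genes passed.

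Of the alternatives for named genes, 532 of 587 kept direction and side of the threshold in epithelial cells, 205 of 309 in macrophages (88 newly passed), 141 of 175 in T cells (32 newly passed), 171 of 197 in fibroblasts, 43 of 59 and 75 of 96 in conventional and plasmacytoid dendritic cells and 43 of 48 in B cells. For shares it was 75 of 84. The limit of 10% mitochondrial UMIs was not run. Clustering each library on its own gave no value for T cells, conventional dendritic cells, B cells and T and NK sub-classes, and leaving out a library of batch 2 none where Placebo 1 is missing. The lowest UMI sums tested were those of B cells (14 cells, 75581 UMIs) and T cells (26 cells, 146342 UMIs) of Progesterone 2.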

Other observations

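The higher T cell share in placebo tumours of both batches, the Calca share inside 1 T cell sub-cluster, and the return of removed cells to the T cells, were tested only after the result was seen.

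Tumour epithelial cells of Placebo 2 carried transcripts of genes better known from liver and gut. Gcg, the glucagon gene, stood at 857 CPM there, and Fgg, a fibrinogen gene, at 164 CPM, against 0.908 and 2.33 CPM in Progesterone 2, but neither passed (adjusted p = 0.191 and 0.108). Tph1, which encodes a serotonin-making enzyme, passed (log2 ratio -1.86), as did Sprr1a, a gene of the cornified envelope (-1.91), and Ereg, an epidermal growth factor receptor ligand gene (-1.58). Gcg, Fgg, Tph1 and Sprr1a are among the genes that lead cluster 2, which held 2256 cells of Placebo 2 and 9 of Progesterone 2 and Progesterone 3 together. These genes were named after their values were seen. A cluster that stayed without a name, led by the muscle genes Acta1, Tnnc2 and Mylpf and the mast cell protease genes Mcpt2 and Mcpt1, held 36, 80, 14, 3 and 5 cells in the order Placebo 1, Progesterone 1, Placebo 2, Progesterone 2 and Progesterone 3.

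T cells made up most of Placebo 1, where 3990 of 4314 haematopoietic cells were T cells and 1 cell was epithelial. Thymus tissue in the library was argued against, since 0 of the 3990 T cells, or 0%, had a UMI of Rag1, which allows up to 0.0752%, and Ptcra and Dntt had 8 and 50 UMIs. An equal loss of myeloid cells in both libraries of batch 1 was argued against, since the T cell share of haematopoietic cells was 63.9 percentage points lower in Progesterone 1. That test holds no tumour cells, so low recovery in batch 1 as a whole stays open. Epithelial cells were 0.0231% and 3.85% of named cells in Placebo 1 and Progesterone 1, against 67.6% or more in each library of batch 2. Macrophages were 0.371% and 19.9% of haematopoietic cells, against 68.3% or more. Lymph node tissue stays open as a hypothesis, since the naive and memory list was higher in T cells of Placebo 1 than in each other library (lowest median log2 ratio 0.83, against Progesterone 1, and 3.02, 2.08 and 3.86 against the others). On the other side, B cells were 3.78% of haematopoietic cells in Placebo 1 against 15.2% in Progesterone 1. The lymph node stroma genes Ccl21a, Ccl19 and Madcam1 had 0 UMIs in T cells of Placebo 1. They had 0 in those of every other library too and mark stroma, so they do not decide. A higher T cell share with placebo in both batches cannot be told apart from lymph node tissue, because in batch 2 the share was 1.53 percentage points above the higher progesterone library, with overlapping intervals.

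Calca was higher in the T cells of all 3 progesterone libraries. Tumour cells captured together with T cells were argued against, since of 27 T cells with a Calca UMI 0, or 0%, had 10 or more UMIs of Krt8, Krt18, Krt19, Epcam and Krt7 (exact upper limit 12.8%), against 10 of all 479 T cells of these libraries. With the scored doublets and the keratin-led sub-cluster put back it was 1 of 30 (upper limit 17.2%). Free RNA of tumour cells in the droplets cannot be told apart, since 0 of 3 libraries had an interval that covered the predicted count (203 UMIs against 18.8, 6 against 1.58 and 9 against 1.88), but the lower limit of 2.20 in Progesterone 2 was under 2 times its prediction. More Calca inside sub-cluster 4 cannot be told apart either, because that sub-cluster was picked for being led by Calca. There a share 6.17 percentage points higher in Progesterone 1 than in Placebo 1 had a Calca UMI after thinning to 3000 UMIs (8 of 122 cells against 1 of 256). In Progesterone 1, 1 T cell held 120 of the 203 UMIs, and Calca stood at 1.76, 8.55 and 5.71 CPM in macrophages of Progesterone 1, 2 and 3 against 48.4, 41 and 27.1 in T cells.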
